A study of Glycine max with 8 samples.

How the data were processed

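MNase hypersensitive sites (MHSs) are stretches of chromatin that micrococcal nuclease, an enzyme that digests exposed DNA, releases as short fragments under light digestion, so they mark open chromatin. The series holds 8 libraries of soybean (Glycine max, cultivar Williams 82), with 2 libraries each from leaf, flower, seed and root. Per the labels' protocols, ground tissue (0.5 g of powder for leaf, 1 g for the other tissues) was fixed with formaldehyde at 1% for 10 min, and nuclei were digested for 10 min with 0.01, 0.03 or 0.1 unit of the enzyme beside an undigested aliquot. DNA shorter than 100 bp was cut from a gel and sequenced. Leaves and roots came from seedlings at an early vegetative stage and seeds from plants past flowering, all raised in a greenhouse with 12 h of light at 28 °C and darkness at 25 °C, whereas flowers came from plants in a field. Growth conditions therefore differ together with tissue for flower. The labels give the pod stage for the seed plants in the seed records and the flowering stage in the other records, and the seed records were followed.

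The authors deposited a list of sites for each library, and those lists are the starting point here. Each line gives a chromosome, a start and an end in base pairs, and the leaf, flower and seed lists add a score for each site. The score is the authors' own value, deposited without a header, and its definition is not given in the sources used here. It was used only to describe, rank or filter sites within a single list. Reads were trimmed with Trimmomatic 0.36 and aligned with BWA 0.7.15-r1140, per the submitters' processing notes. The site caller, its threshold and the genome build are not given in the sources used here. The number of reads per library is unknown, since the lists hold sites and not reads, so the precision that sequencing depth gives cannot be stated. Lists from an undigested control were not used here.

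The root lists differ in form from the other 6. They are separated by spaces, carry no score, and keep sites down to 49 bp, whereas the shortest site in the leaf, flower and seed lists is 100 bp. Every line of chromosome 11 occurs a second time in both root lists. The repeated lines, 479 in root 1 and 649 in root 2, were removed, which left 15185 and 18957 sites. Site identifiers in each list skip numbers, and the sites listed make up between 33.6% of the identifiers (seed 2) and 48.8% (leaf 1), so each list holds a part of a longer numbered series. Starts were taken to count from 0, as in BED files, and are printed counting from 1. Only the 20 numbered chromosomes occur in the lists, and their span, taken as the last site end per chromosome over all libraries, sums to 948.9 Mb.

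No genome sequence was used here. A table of 47068 protein-coding genes of the assembly Glycine_max_v4.0 was compared with the lists, and it did not match their coordinates. Of the leaf 1 sites, 15.7% lay within 500 bp of a gene end, against 15.0% after the sites had been shifted, and on 4 of 20 chromosomes sites lay more than 100 kb past the last gene. The planned comparisons of sites with transcription start sites, gene groups, base content and sequence motifs were therefore not run, and regions are named by position in place of genes. The rule for named regions took, per tissue, the 5 longest tissue-specific sites and, over tissues, the 3 longest regions shared by 4 tissues, with ties broken by score where a list has one and otherwise by chromosome and start. No tie decided which regions were named.

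Sites of different libraries were said to meet when they overlapped by at least 1 bp. The reproducible MHSs of a tissue are the intersected regions of its libraries that span at least 20 bp. A reproducible MHS is called tissue-specific when it meets no site in any of the 6 libraries of the other tissues. Reproducible MHSs of the 4 tissues were merged into a union, and each merged region was assigned to the combination of tissues it holds. The overlap expected by chance was taken from 20 draws in which the sites of the other list were shifted by 20 to 200 kb. Intervals for shares of sites are 95% Wilson intervals and cover counting error only.

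Replicate concordance was measured with the base-pair Jaccard index, the length shared by a pair of libraries divided by the length covered by either. The mean index of the 4 same-tissue pairs was compared with all 105 ways of pairing 8 libraries in an exact one-sided permutation test. The labels do not say whether libraries of a tissue came from separate plants, so p-values measure the spread between these libraries, which may be technical. A comparison of a tissue with another, 2 libraries against 2, cannot go below p = 0.333 in a two-sided exact test, so no such test is reported. This test, the set definitions and the named-region rule were fixed before the data were examined.

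The outer-to-inner ratio and the window test were chosen after the lists had been seen. The outer part of a chromosome is the 20% of its span at each end and the inner part the 60% between. The ratio is the number of sites per Mb in the outer part over that in the inner part, and its log2 was compared between tissues with an exact one-sided permutation test of the sum of squares between pairs over the same 105 pairings. Per-chromosome ratios, with 0.5 added to each count, were compared between sets of regions by a two-sided sign-flip permutation test over 20 chromosomes with 100000 resamples and Benjamini-Hochberg adjustment over 10 contrasts. Chromosomes of the same libraries are not independent samples of plants. Windows of 100 kb with at least 5 union regions were tested for an excess of tissue-specific regions with a one-sided Fisher's exact test and Benjamini-Hochberg adjustment at 0.05, with regions as the units.

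Alternatives were each library left out in turn, an overlap of at least 50% of the shorter region, stricter lists, equal numbers of sites per library, another measure of concordance, pairings within replicate numbers, a looser definition of specific sites, analyses without root, root sites of at least 100 bp, other limits of the outer part and other window sizes. The stricter lists kept the upper 50% of sites by score, or, for root, sites at least as wide as the median. Equal numbers meant 15185 sites per library, taken by score or, for root, drawn at random.

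Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and overlap counts were checked against bedtools 2.31.1. The scripts were tested on simulated data. In simulated lists, 100.0% of 19922 common sites were recovered. For the window test, 7833 windows were simulated at each tissue's own share of specific sites, of which 5259 held the 5 regions needed for a test. In these simulations 200 windows, drawn from those with more regions than that minimum, were given 5 times the odds of specific sites. Of these, 13.0% were called for leaf, 1.0% for flower, 13.5% for seed and 0% for root, and without such windows 0 were called for any tissue. Of the calls, 3.57% for seed and 0% for leaf and flower were windows with no added sites. For root 0 windows were called, so no such share exists.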

Results

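Open chromatin was mapped in 4 soybean tissues as MNase hypersensitive sites, with 2 libraries per tissue and a separate site list per library. Leaf gave 75471 and 74278 sites, seed 82798 and 63243, flower 50078 and 62094, and root 15185 and 18957. Leaf sites covered 17.3 and 16.3 Mb of the 948.9 Mb spanned, seed sites 17.1 and 11.7 Mb, flower sites 9.59 and 12.4 Mb, and root sites 1.33 and 1.56 Mb. The mean number of sites was 74875 ± 844 (SD, n = 2) in leaf, 73021 ± 13827 (SD, n = 2) in seed, 56086 ± 8497 (SD, n = 2) in flower and 17071 ± 2667 (SD, n = 2) in root. Leaf and seed differed by less than the spread of the seed libraries, both flower libraries lay below all leaf and seed libraries, and both root libraries lay below all others. Median site width was 201 and 190 bp in leaf, 183 and 164 bp in seed, 167 and 172 bp in flower, and 69 and 67 bp in root. Of the root sites, 79.0% and 82.3% were shorter than 100 bp, a width class that the other lists do not contain. The read depth behind the lists is unknown.

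Sites were unevenly divided among chromosomes in leaf, flower and seed. Chromosome 13 held the most, with a mean of 105.1 sites per Mb over the 6 libraries (range 80.0 to 124), followed by chromosome 11 with 96.1 and chromosome 17 with 89.0. Chromosome 14 held the fewest by this mean, 57.7 per Mb (range 42.3 to 72.6), and chromosomes 18 and 1 held 58.1 and 58.4. Which of these was lowest differed between libraries, with chromosome 18 at 41.4 in flower 1 and chromosome 1 at 61.3 in leaf 2. On every chromosome the ranges across libraries reflect list lengths, so ranks of the mean and not levels are compared.

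The first comparison asked whether libraries of a tissue shared more site sequence than libraries of different tissues. The leaf libraries shared most, with a base-pair Jaccard index of 0.605, followed by flower at 0.417, seed at 0.380 and root at 0.157. Leaf 1 sites were met by leaf 2 in 79.4% of cases (95% Wilson interval 79.1 to 79.7), against 6.16% for shifted sites. Seed 2 sites were met by seed 1 in 75.2% (74.9 to 75.6) and seed 1 sites by seed 2 in 56.4% (56.1 to 56.7), while for flower the shares were 74.3% and 59.3%. Root sites were met by the other root library in 25.4% (24.7 to 26.1) and 20.7% (20.1 to 21.2), against 1.08% and 0.834% for shifted sites.

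The mean index of the 4 same-tissue pairs, 0.390, was the highest of all pairings of the 8 libraries (exact one-sided permutation p = 0.00952, the smallest these pairings allow), and the next pairing reached 0.334. Pairs of libraries from different tissues averaged 0.188, pulled down by pairs with root. The root lists cover only 1.33 and 1.56 Mb, so length alone keeps their index with the longer lists low. Pairings that split the root libraries were thus at a disadvantage in advance, and the p-value partly reflects list length. For 7 of 8 libraries the nearest library was the other of the same tissue. Seed 1 was the exception, with an index of 0.426 to leaf 1 against 0.380 to seed 2. By observed over expected shared bases, which scales by the length each library covers, the same-tissue library was nearest for 8 of 8. Without root the same-tissue mean was 0.467, again the highest, against 0.341 for pairs of different tissues. The 15 pairings of 6 libraries cannot go below p = 0.0667 in the exact test.

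**Figure D1:**
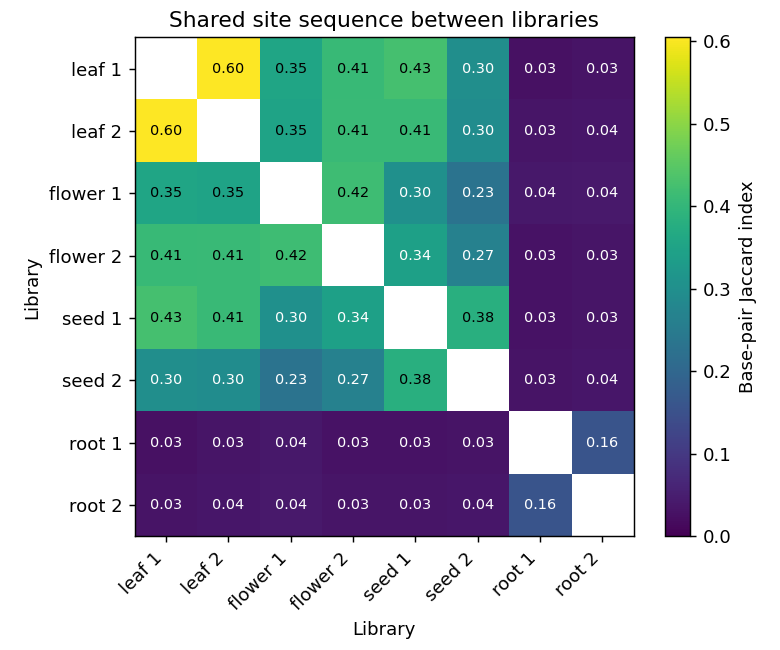
Base-pair Jaccard index for each pair of the 8 libraries, as a heat map with both axes listing libraries and the index printed in each cell. The leaf pair is highest at 0.605, and every index between a root library and another tissue is at most 0.0422.

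Between tissues, leaf and flower were the closest by observed over expected shared bases, and pairs of root with another tissue the lowest. Expected bases assume sites spread evenly over the span, so lists that crowd in the same chromosome parts reach higher values for that alone. Shifted regions keep that crowding, and against them the pairs with root were not the lowest. Each pair with root exceeded its shifted share by a larger factor than any pair without root. Of the reproducible root regions, 46.1% met leaf against 1.73% shifted, and of the leaf regions 48.5% met flower against 2.70% shifted. Against shifted regions leaf and flower did not lead the pairs without root either. Of the flower regions, 57.1% met seed against 2.86% shifted, a larger factor than for leaf, at 81.8% against 4.43%. The log2 ratio of observed to expected shared bases averaged 5.31 for the 4 leaf and flower library pairs (range 5.25 to 5.35), 5.09 for flower and seed (5.05 to 5.17) and 5.01 for leaf and seed (4.97 to 5.05). The leaf and flower values lay above all 8 values of the other comparisons among these tissues. By the Jaccard index they did not: leaf and flower pairs ran from 0.351 to 0.410 and leaf and seed pairs from 0.295 to 0.426. By log2 observed over expected bases, pairs with root averaged 4.49 for leaf, 4.70 for flower and 4.55 for seed, all below the range of the pairs without root. The 2 root libraries had the highest value of all, 7.49, on the smallest covered length.

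Reproducible MHSs numbered 61056 in leaf, 47979 in seed, 37701 in flower and 3869 in root. Flower regions were mostly shared with leaf: 81.8% met a reproducible leaf region, against 4.43% ± 0.0976 (SD over 20 shifts) for shifted regions, and 57.1% met a seed region. Of the leaf regions, 48.5% met flower and 51.7% met seed, and of the seed regions 68.5% met leaf and 45.2% met flower. Root regions met leaf in 46.1%, seed in 38.4% and flower in 32.3%, against 1.73%, 1.11% and 0.871% for shifted regions. These shares move with the number of regions in the set that is met.

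Merging the reproducible regions of the tissues gave 82398 regions. Of these, 19648 (23.8%) were reproducible in leaf, flower and seed, with or without root, and 39540 (48.0%) in a single tissue. A region reproducible in a single tissue can still meet a site in 1 library of another, as most did in leaf, where 19204 regions were reproducible in leaf alone and 5871 met no site elsewhere. Leaf and seed without flower or root shared 11274, leaf and flower without seed or root 9602, and flower and seed without leaf or root only 1523. Regions reproducible in all 4 tissues numbered 1050 (1.27%). The count was 3539 without root 1, 3042 without root 2, 454 with root sites of at least 100 bp, 520 with stricter lists and 345 with equal numbers of sites. Their median width was 317 bp, against 285 bp for the 18598 regions of leaf, flower and seed without root, and 139 bp for the 19204 regions of leaf alone. These are widths of merged regions, which can only grow as sites of more tissues are merged, so their order is partly set in advance.

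**Figure D2:**
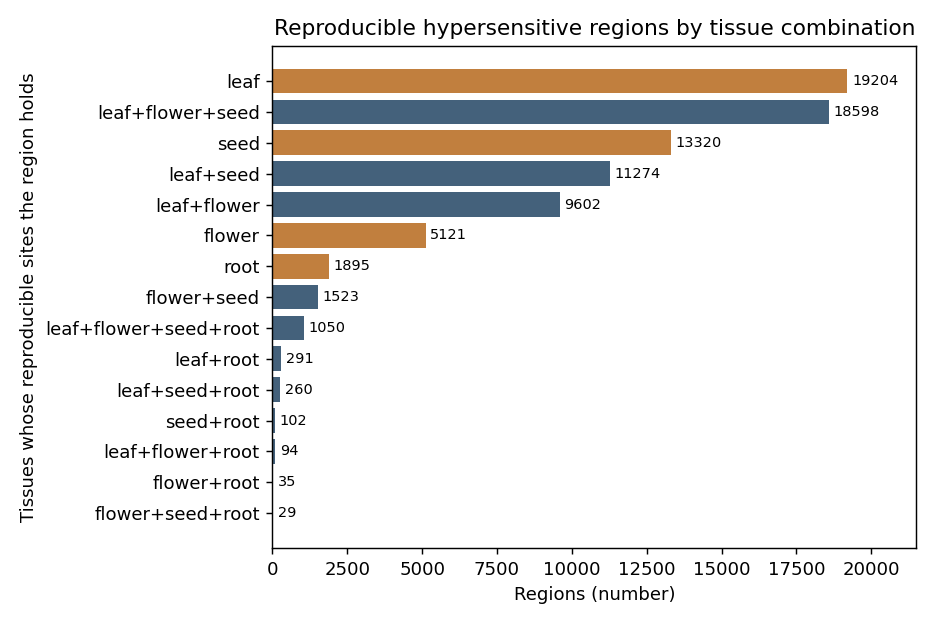
Number of merged regions (horizontal axis) for each of the 15 combinations of tissues whose reproducible sites they hold (vertical axis), with regions reproducible in a single tissue in orange. Regions reproducible in leaf alone (19204) and leaf with flower and seed (18598) are the most frequent classes, and each class with root other than root alone holds at most 1050 regions.

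The longest regions reproducible in all 4 tissues lay close together on chromosome 15. The region at 19588801 to 19592289 spanned 3489 bp, and each of the 8 libraries held a single site of 3464 to 3496 bp there, which was the widest site of each list. The next, at 19586846 to 19588510 on the same chromosome, spanned 1665 bp, with sites of 1636 to 1671 bp in the 8 libraries. The next after these lay on chromosome 19 at 5356265 to 5357518 and spanned 1254 bp. In the 6 scored lists these 3 regions ranked above percentile 99.9 of their list by score. The scores at 19588801 on chromosome 15 were 3.32 and 3.52 in leaf, 5.17 and 3.31 in flower, and 5.20 and 6.38 in seed, on scales that need not be the same.

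**Figure D3:**
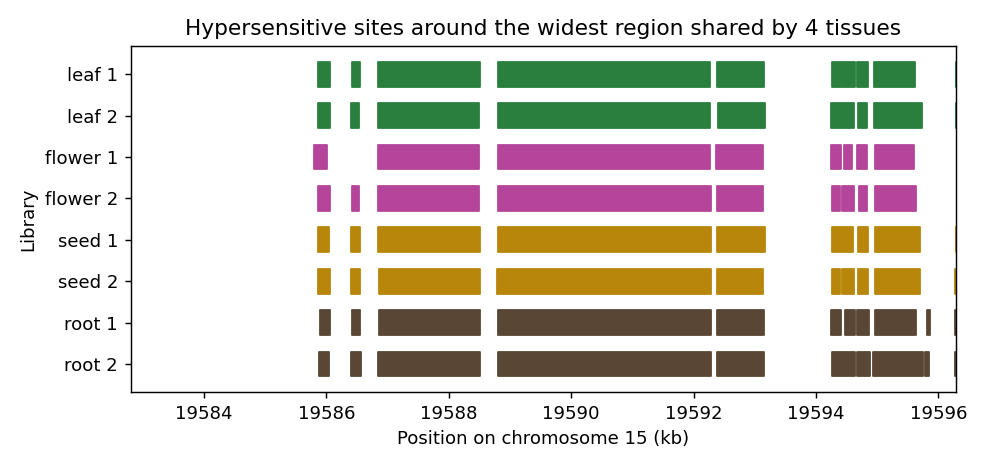
Sites of the 8 libraries (vertical axis) along chromosome 15 from 19582801 to 19596289 (horizontal axis, kb), each bar a deposited site. The bars at 19588801 to 19592289 span 3464 to 3496 bp in every library.

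A position absent from a list need not be closed chromatin, since the calling threshold is unknown. Tissue-specific sites, listed in both libraries of a tissue and in no library of another, numbered 5871 in leaf (9.62% of its reproducible MHSs), 6297 in seed (13.1%), 1777 in flower (4.71%) and 1045 in root (27.0%). They were narrower than the tissue's other sites, with a median of 124 bp in leaf against 183 bp for all reproducible leaf regions, 114 against 151 bp in seed, 109 against 153 bp in flower and 64 against 76 bp in root. The high root share rests on narrow sites that the other lists do not hold. With root sites of at least 100 bp, 175 of 1482 reproducible root regions were specific, a share within the range of the other tissues. Leaving out a library of the tissue itself raised the counts to 11201 and 11228 in leaf, 14872 and 17843 in seed, 7875 and 5516 in flower, and 9929 and 7550 in root (without replicate 1 and without replicate 2), and without seed 1 the leaf count was 9496. Stricter lists kept the order of the tissues, with 3961 in seed, 3031 in leaf, 1125 in flower and 1087 in root. The order changed with 15185 sites in every library, the highest-scoring ones or, for root, a random draw, which gave 996 in leaf, 1553 in seed, 1177 in flower and 1750 in root. It changed as well without either library of leaf, flower or root: without leaf 1, leaf (11201) lay above seed (7946), without flower 2, leaf (7982) above seed (7449), without flower 1, flower (7875) above leaf (6816) and seed (6774), and without root 1, root (9929) above seed (6420). It also changed when only reproducible sites of the other tissues could exclude a site, with 19204 in leaf, 13320 in seed, 5121 in flower and 1895 in root.

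The longest leaf-specific site lay on chromosome 10 at 39051107 to 39051804 and spanned 698 bp. It was followed by chromosome 2 at 41774841 to 41775372 (532 bp), chromosome 20 at 1282021 to 1282543 (523 bp), chromosome 2 at 15220526 to 15221046 (521 bp) and chromosome 10 at 49418093 to 49418598 (506 bp). The site on chromosome 20 stood at percentile 90.3 of scores in leaf 1 and percentile 78.4 in leaf 2, and the site at 39051107 on chromosome 10 at percentiles 71.8 and 72.8. The site at 49418093 on chromosome 10 stood at percentile 46.5 in leaf 2, below the middle of that list.

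In seed, the longest specific site lay on chromosome 10 at 47770817 to 47771280 and spanned 464 bp. The others lay on chromosome 1 at 30013094 to 30013532 (439 bp), chromosome 19 at 435440 to 435850 (411 bp), chromosome 8 at 426463 to 426839 (377 bp) and chromosome 14 at 44870235 to 44870611 (377 bp). The site on chromosome 8 stood highest of these 5 by score, at percentile 94.6 in seed 1 and percentile 97.4 in seed 2. The site on chromosome 19 stood at percentiles 94.1 and 84.2.

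Flower-specific sites were shorter. The longest lay on chromosome 12 at 10515125 to 10515450 and spanned 326 bp, followed by chromosome 19 at 49282522 to 49282814 (293 bp), chromosome 2 at 37116458 to 37116746 (289 bp), chromosome 6 at 9780458 to 9780740 (283 bp) and chromosome 12 at 2505599 to 2505879 (281 bp). The site on chromosome 2 stood at percentile 71.2 in flower 1 and percentile 91.7 in flower 2. The longest site, on chromosome 12, stood at percentile 47.4 in flower 1 and percentile 69.1 in flower 2.

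Root-specific sites were the shortest. The longest lay on chromosome 6 at 32113049 to 32113302 (254 bp), chromosome 4 at 28328919 to 28329167 (249 bp), chromosome 15 at 45194067 to 45194287 (221 bp), chromosome 10 at 19033614 to 19033832 (219 bp) and chromosome 20 at 14299653 to 14299871 (219 bp). The site on chromosome 15 lay in the outer part of its chromosome and the other 4 in the inner part. With root sites of at least 100 bp alone, 175 root-specific sites were left of 1045.

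Shared sites had higher scores than tissue-specific ones within each scored list. In leaf 1, sites in regions reproducible in leaf, flower and seed had a median at percentile 80.7 of scores and leaf-specific sites at percentile 32.1, and in leaf 2 the median percentiles were 79.4 and 31.8. The corresponding medians were 65.2 and 34.8 in flower 1, 73.1 and 39.3 in flower 2, 78.5 and 39.5 in seed 1, and 65.1 and 44.4 in seed 2. The direction was the same in 6 of 6 lists. The definitions set part of this in advance, since shared regions had to be listed in all 6 scored libraries and specific sites in no library of another tissue. Replicate overlap rose with score as well: in the lowest score decile of leaf 1, 43.3% of the sites were met by leaf 2, and in the highest 99.9%. In seed 1 the shares were 27.5% and 92.9%.

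**Figure D4:**
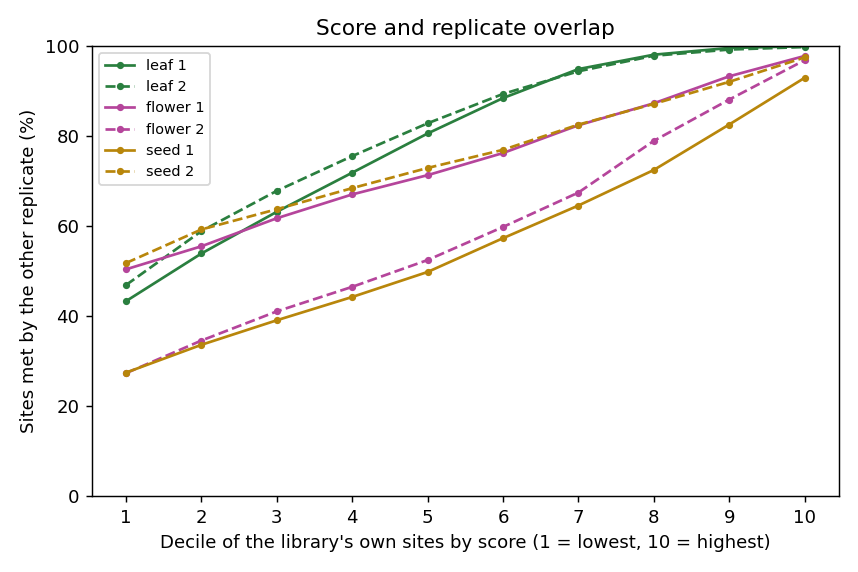
Share of sites met by the other library of the tissue (vertical axis, %) in each decile of a list by its own score (horizontal axis), for the 6 scored libraries. The share climbs from 27.3% to 96.8% in flower 2 and from 43.3% to 99.9% in leaf 1.

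Pooled over the chromosomes, leaf, flower and seed sites crowded towards the ends more than root sites did. The outer 20% at each end held 3.20 and 3.13 times as many leaf sites per Mb as the inner part, 3.22 and 3.30 times as many flower sites, and 2.85 and 2.62 times as many seed sites. In root the ratios were 0.984 and 1.24, so that only root 2 was denser in the outer parts. As tissue means, the log2 ratios were 1.66 in leaf, 1.70 in flower, 1.45 in seed and 0.14 in root, with a range of 1.56. The sign of the root value is not settled: it was 0.31 without root 1, -0.023 without root 2, -0.082 with stricter lists and -0.60 with root sites of at least 100 bp. With libraries paired by tissue, the sum of squares between pairs of the log2 ratios was the largest of all pairings of the 8 libraries (exact one-sided permutation p = 0.00952). Both root libraries lay below all 6 others on 19 of 20 chromosomes. The exception was chromosome 13, where the order was reversed: the ratios of the leaf, flower and seed libraries ran from 0.757 to 0.880, so that their sites did not favour the ends, and those of root were 1.65 and 1.40. Both seed libraries lay below all 4 leaf and flower libraries on 19 of 20 chromosomes, with chromosome 20 as the exception. Without root the range was 0.25 and the sum of squares between pairs was again the largest, but 15 pairings cannot go below p = 0.0667 in the exact test.

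**Figure D5:**
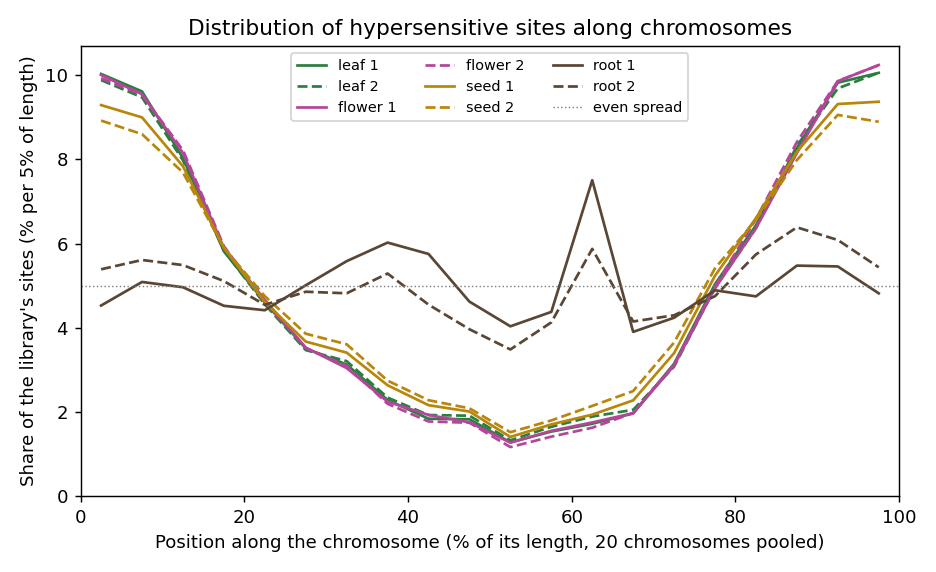
Share of each library's sites (vertical axis, %) in 20 equal parts along the chromosomes (horizontal axis, % of length), pooled over 20 chromosomes, with solid lines for replicate 1 and dashed lines for replicate 2. Leaf, flower and seed lie highest towards both ends, while root 2 rises less, with an outer-to-inner ratio of 1.24, and root 1 has a ratio of 0.984.

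The tissue-specific sets followed the same order as the lists except that leaf came first. The outer-to-inner ratio was 4.01 for leaf-specific, 3.62 for flower-specific, 2.06 for seed-specific and 0.281 for root-specific sites, and 3.04 for regions shared by leaf, flower and seed. The log2 ratio of leaf-specific sites exceeded that of seed-specific sites by 1.16 ± 0.47 (SD over 20 chromosomes), in the same direction on 20 of 20 chromosomes (sign-flip permutation p = 4.0e-05, adjusted 5.0e-05 over 10 contrasts). Flower-specific sites exceeded seed-specific sites by 1.07 ± 0.59, on 20 of 20 chromosomes (permutation, adjusted p = 5.0e-05). Leaf-specific and flower-specific sites differed by 0.09 ± 0.42, with leaf higher on 13 of 20, which did not pass the permutation test (adjusted p = 0.353). Seed-specific sites lay below the shared regions on 20 of 20 chromosomes, with a difference of -0.67 ± 0.30 (permutation, adjusted p = 5.0e-05).

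Root sites also gathered in certain inner windows. The window of 1 Mb on chromosome 5 that starts at 16000001 held 260 root 1 and 174 root 2 sites, and 8 to 67 sites of the other libraries. The windows that start at 20000001 on chromosome 2, at 14000001 on chromosome 20 and at 32000001 on chromosome 6 held 187 and 162, 204 and 140, and 180 and 159 root sites. The 6 densest inner windows held 7.91% of root 1 and 4.74% of root 2 sites, and without them the outer-to-inner ratios were 1.13 and 1.36. Leaf 2 was dense in these windows too, with 62 to 108 sites against a mean of 42.2 per Mb in its inner parts, whereas leaf 1 exceeded its inner mean in 3 of the 6 windows, flower 1 and seed 2 in 2, seed 1 in 1 and flower 2 in 0. These windows were chosen after their counts had been seen.

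In windows of 100 kb, 90 of 5259 held an excess of root-specific regions (Fisher's exact test, Benjamini-Hochberg), and 82 of these lay in inner parts. The 90 windows held 528 (50.5%) of the root-specific sites. Each window was set against the share over all windows, whereas root-specific sites had an outer-to-inner ratio of 0.281 and shared regions 3.04. Inner windows therefore passed more readily, and their number partly restates that distribution. The count was 15 with root sites of at least 100 bp, 167 without root 1 and 179 without root 2. On chromosome 10, 25 of 32 regions at 18900001 to 19000000 were root-specific (Fisher's exact test, adjusted p = 4.65e-38), as were 18 of 30 in the next window (adjusted p = 1.23e-23). Root 1 had 50 sites in the former and root 2 had 75, while the other libraries had 1 to 13. On chromosome 9, 10 of 12 regions at 44600001 to 44700000 were root-specific, and only flower 1 among the other libraries had sites there, 2 in number.

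Flower-specific regions were in excess in 3 windows, all in inner parts. On chromosome 19 at 12700001 to 12800000, 5 of 7 regions were flower-specific (Fisher's exact test, adjusted p = 0.000494). On chromosome 17 at 23500001 to 23600000 it was 7 of 23 (exact test, adjusted p = 0.00102), with 30 and 26 flower sites against 12 and 15 in leaf and 19 and 13 in seed. On chromosome 12 at 24200001 to 24300000 it was 6 of 17 (exact test, adjusted p = 0.00176), with 17 and 24 flower sites against 5 and 12 in leaf. At equal numbers of sites 0 flower windows passed, with stricter lists 1, and with windows of 200 kb 5.

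Leaf-specific regions were in excess in 2 windows, on chromosome 9 at 44200001 to 44300000 (9 of 22) and on chromosome 13 at 22400001 to 22500000 (11 of 33), both with an adjusted p of 0.0277. Leaving out leaf 1 or seed 1, using equal numbers of sites, or windows of 50 or 200 kb, left 0 leaf windows, whereas 4 passed without flower 1 and 5 without seed 2. In seed 0 windows passed Fisher's exact test after adjustment, with 242 at an unadjusted p under 0.05, but 3 passed without leaf 2 and 2 with windows of 200 kb. The seed window nearest to the threshold, on chromosome 18 at 42300001 to 42400000, had 5 of 6 regions seed-specific (exact test, adjusted p = 0.0769). On simulated windows with 5 times the odds, the test recovered 13.5% for seed-specific and 1.0% for flower-specific sites, so windows that did not pass are not shown to be without an excess.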

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

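The comparison of outer and inner density was chosen after the site lists had been seen, and so were the tests without root and with root sites of at least 100 bp. The tests of the explanations below had their predictions written before their results. The distribution along chromosomes differed between the 4 tissues (exact permutation p = 0.00952 over all pairings of the 8 libraries for the sum of squares between pairs). Without root this sum was again the largest, but the 15 pairings left cannot go below p = 0.0667 in the exact test.

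Pooled over chromosomes, root sites were less concentrated in the outer parts than those of the other tissues, with ratios of 0.984 and 1.24 against at least 2.62 elsewhere. The narrow sites kept in the root lists do not account for this, since root sites of at least 100 bp had lower ratios still, 0.558 and 0.782. For background calls, the written prediction was that root sites not met by the other root library are evenly spread, within a set bound. This held in root 1 (1.14) but not in root 2 (1.47). Sites met by the other library and another tissue were also to be more outer than sites met by no library. They differed by log2 0.25 in root 1 and -0.36 in root 2, in opposite directions, so this test cannot decide. Root sites that met the other root library had ratios of 0.620 and 0.615, a comparison not among the predictions. Calls scattered by chance are thus not the only source of the pattern, but background that recurs at the same places in both libraries cannot be told apart from root chromatin. Sites found in both root libraries and in no other made up 6.90% and 5.58% of the lists. This was under the 20% written down beforehand for another distribution of open chromatin in roots. Only 25.4% and 20.7% met the other root library at all, so that bound could hardly be reached. The prediction also asked these sites to be spread as evenly as the whole list, and they were not. Their ratios were 0.286 and 0.279, against 0.984 and 1.24 for the lists. Leaving out sites met by tissues that favour the ends lowers their ratio in advance, so neither part decides and the explanation stays open. Root lists also differed from the others in form, with no score and with sites down to 49 bp, so tissue and processing may not be separable here.

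A larger share of the seed sites lay in inner parts than of the leaf and flower sites. The number of called sites does not account for it, since with equal numbers of highest-scoring sites the seed ratios were 2.66 and 2.40 against at least 3.12 in leaf and flower. Strength could not be made equal this way, since score scales need not be the same between lists and read depth is unknown. A few dense inner windows do not account for it either, since without the densest 1% of inner windows the seed ratios were 2.98 and 2.73 against at least 3.29. Both seed libraries lay below all 4 leaf and flower libraries on 19 of 20 chromosomes, but any cause common to both seed libraries would give this, so a difference between tissues and handling that differed between seed and the other tissues cannot be told apart, and both stay open.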

How the results depend on the processing

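The outer and inner ratios, the window tests, the settings without root for concordance, and root sites of at least 100 bp were chosen after the data had been seen, and the other alternatives were planned. Of 270 alternative values of 24 results, 199 kept their call, 66 moved, 2 were weaker and 3 turned sign. A call is kept when a test stays on its side of the threshold in the same direction, a count of regions or windows stays within 1.5 times, or a log2 ratio or mean number of listed sites moves by less than the SD between libraries, so a small move in a ratio can count as moved. Concordance passed the exact permutation test under each alternative with 4 tissues, though by the Jaccard index the short root lists held back pairings that split them. The difference between leaf-specific and seed-specific sites passed its permutation test under each alternative that was run. Replicate numbers do not pair the libraries (correlations of deviations from -0.00460 to 0.0164), and with a replicate block of 24 pairings both concordance (0.390) and the outer and inner ratios (range 1.56, tested by the sum of squares between pairs) had an exact permutation p of 0.0417, the smallest it allows, so the block changed no call. Without root, concordance was 0.467 and the range 0.25, both tests had an exact p of 0.0667, the smallest that the 15 pairings left allow, and 19652 regions were shared by the tissues left.

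Stricter lists, about 50% as long by construction, gave mean site numbers of 37438 in leaf, 28043 in flower, 36511 in seed and 8629 in root, with 28947, 17292 and 21174 reproducible and 3031, 1125 and 3961 specific sites in leaf, flower and seed, 520 regions shared by 4 tissues, and 1 leaf and 1 flower window. The log2 ratio of root, 0.14, became -0.082. Equal numbers gave 996 leaf-, 1177 flower-, 1553 seed- and 1750 root-specific sites, 345 shared regions, and 0 leaf and 0 flower windows. Compared with reproducible sites only, specific sites numbered 19204 in leaf, 5121 in flower, 13320 in seed and 1895 in root, since fewer sites could exclude them. Root sites of at least 100 bp averaged 3274 per library, with 1482 reproducible, 175 specific, 454 shared, 15 root windows and a log2 ratio of -0.60. Windows of 50 kb gave 0 leaf windows, and windows of 200 kb gave 0 leaf, 5 flower and 2 seed windows. An outer part of 10% or 30% gave log2 ratios of 1.37 or 1.81 in leaf, 1.39 or 1.89 in flower and 1.18 or 1.59 in seed, and ranges of 1.29 or 1.83. An overlap of at least 50% gave 6615 leaf-specific and 996 shared regions, and log2 observed over expected bases a concordance of 5.96. The cause of the changes in windows and root ratios was not tested.

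Leaving out a library lets the other stand for its tissue, so its sets grow, and the highest values below come from leaving out a library of the tissue itself unless another is named. Without seed 1, leaf-specific sites numbered 9496. Specific sites ranged from 5928 to 11228 in leaf, 1798 to 7875 in flower, 6420 to 17843 in seed and 1057 to 9929 in root, and reproducible sites from 37701 to 62094 in flower, 47979 to 82798 in seed and 3869 to 18957 in root. Shared regions ranged from 1058 to 3539 (highest without root 1), windows from 0 (without leaf 1 or seed 1) to 5 (without seed 2) in leaf, 0 to 3 in seed (3 without leaf 2) and 94 to 179 in root, and the log2 ratio of root from -0.023 (without root 2) to 0.31 (without root 1).

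The alternatives listed beforehand for transcription start sites, base content, gene groups, motifs and promoters were not run, since no matching genome was used here. Read depth is unknown, so how far it limits the shorter lists cannot be said.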

Other observations

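The neighbourhood and score values below were chosen after the data had been seen. Tissue-specific sites lay near shared regions more often than shifted sites did. Within 2 kb of a region reproducible in leaf, flower and seed lay 19.5% of the leaf-specific sites, against 15.6% ± 0.537 (SD over 20 shifts), and 22.5% of the flower-specific sites, against 15.5% ± 0.786. For seed-specific sites the shares were 17.1% against 12.3% ± 0.389, and for root-specific sites 9.09% against 4.07% ± 1.00. In all 4 tissues the observed share lay above the highest of the 20 shifts.

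Root sites that met a leaf, flower or seed site but not the other root library made up 31.8% of root 1 and 32.5% of root 2, and their outer-to-inner ratios were 2.28 and 2.60, below the lowest leaf, flower or seed library at 2.62. Overlap with sites that favour the ends sets part of that ratio in advance. Root sites that met both the other root library and another tissue had ratios of 0.780 and 0.774, and those that met the other root library alone 0.286 and 0.279. Regions reproducible in leaf and root but not in flower or seed, 291 in number, had a ratio of 0.267, against 3.94 for the 9602 regions reproducible in leaf and flower alone.

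A few sites had scores far above the rest of their list. On chromosome 13 at 7358781 to 7359564, the highest scores were 39.9 and 22.4 in leaf, 32.9 and 16.8 in flower and 37.4 and 25.2 in seed, while the median score was 0.232 in leaf 1 and 0.259 in flower 1. Both root libraries had a site of 220 bp there. On chromosome 18 at 10398136 to 10398384 the score was 82.1 in leaf 2, 127 in flower 1 and 18.6 in seed 1, but 1.44 in leaf 1, 0.524 in flower 2 and 1.68 in seed 2. In flower 2 that site stood at percentile 99.0 of its list, and in flower 1 it was the highest of all. The scales of the lists need not be the same.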
